A study of Mus musculus with 10 samples.

How the data were processed

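Livers of Etnppl knockout and wild-type female mice on a chow diet were snap frozen, and poly-A RNA of 5 samples per genotype was sequenced in paired ends, per the labels. The deposited table gave FPKM, fragments scaled by transcript length and library total, per gene and library, as computed by the authors. STAR, RSEM, R 4.0.2, DESeq and DESeq2 and the mm10 build are named in the submitters' processing notes, without a role for each. The annotation release and the strand setting were not given in the sources used here, although the labels' protocols name a directional second-strand step. Overlapping and antisense genes can therefore share reads. FPKM is relative to each library's total, so a rise in abundant transcripts lowers the rest.

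The labels name each sample by genotype and replicate number. They do not say that each is a single animal, so p-values measure the spread between these samples. No 2 libraries held identical values. Spearman correlations across genes ranged from 0.977 to 0.988 within and from 0.974 to 0.983 between genotypes. The first principal component held 27.4% of the variance and separated the genotypes.

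Values were used as deposited, as log2(FPKM + 0.5), so fold changes of low genes are understated. Genes with a mean of at least 0.5 FPKM over all 10 libraries were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options, genotype as the only term, two-sided), and called at a Benjamini-Hochberg adjusted p under 0.05. FPKM is not a count, so no count model was used. Of 712 gene list entries, 707 matched a gene of the table, some through older symbols. The 39 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Single values were compared with exact permutation tests of the 252 arrangements. Gene positions, lengths and GC content came from a GRCm38 annotation, the assembly of mm10.

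Named genes were fixed by rule before the data were examined. They were Etnppl, the 10 called genes with the largest rise and the 10 with the largest fall among those with at least 1 FPKM in the higher group and no overlap between genotypes, up to 6 called genes within 10 Mb of Etnppl by p, and in each described list the 4 members with the smallest p, with any called member where the list had 6 or fewer. Genes named outside this rule are said to be, and some that the rule gives are not reported here.

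Total reads per library were not analysed here. Relative depth was estimated from 134 genes with low FPKM, whose values in a library are multiples of what 1 fragment is worth. Of their values, 96.4% lay within 0.15 of a step from a whole number. Simulated libraries of 1500 low genes, made of whole fragments only, returned their known depths within 0.08%. That error need not hold for the 134 genes used. The fit was tested on simulated data for KO against WT with 12247 genes, 200 of them changed. A further 20 were shifted by 0.3 on the log2 scale and not counted as false calls. The fit recovered 62.8% of genes changed by 0.5 on the log2 scale, 90.2% of those changed by 1 and 99% of those changed by 2, with 4.36% false calls. With no gene changed it made 0 calls. The simulated noise was independent between genes, so these rates need not hold where genes vary together.

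Alternatives were other pseudocounts and filters, 3 scalings, non-robust fits, library weights, the replicate number as a block, each library left out in turn, a fold minimum, an estimated correlation or fry for lists, and other distances from Etnppl. Trends on length and GC were fitted with mgcv 1.9.3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.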

Results

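Liver RNA was measured in female mice that carried a whole-body knockout (KO) of Etnppl and in wild-type (WT) females. All animals ate a chow diet for 20 weeks. Etnppl encodes ethanolamine-phosphate phospho-lyase, an enzyme that breaks down phosphoethanolamine, an intermediate of phosphatidylethanolamine synthesis. Each genotype had 5 libraries of poly-A RNA, and the values were FPKM for 47702 genes, of which 12247 had a mean of at least 0.5 FPKM and were tested. The number of reads per library was not given in the sources used here. Relative depth, read from the steps between low values, ranged from 0.901 in KO 4 to 1.104 in WT 3. It averaged 1.051 in WT and 0.9536 in KO (exact permutation test, two-sided, p = 0.048, n = 5 and 5).

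Etnppl transcript was lower in every KO library than in every WT library, but it was not absent. The gene (ENSMUSG00000019232) lies on the plus strand of chromosome 3 from 130617448 to 130637521 in mm10. Its level was 65.8 ± 26 FPKM (SD, n = 5) in WT, with values from 43.32 to 108.39, and 22.1 ± 3.92 FPKM (SD, n = 5) in KO, with values from 17.72 to 26.43. The KO mean was 33.7% of the WT mean. The log2 difference was -1.49 (SE 0.23, limma adjusted p = 0.005). The exact two-sided permutation test gave p = 0.0079, the smallest that the 252 arrangements of 5 and 5 libraries allow. FPKM per gene does not show which part of the transcript remained, and the targeted exons were not given in the sources used here.

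**Figure D1:**
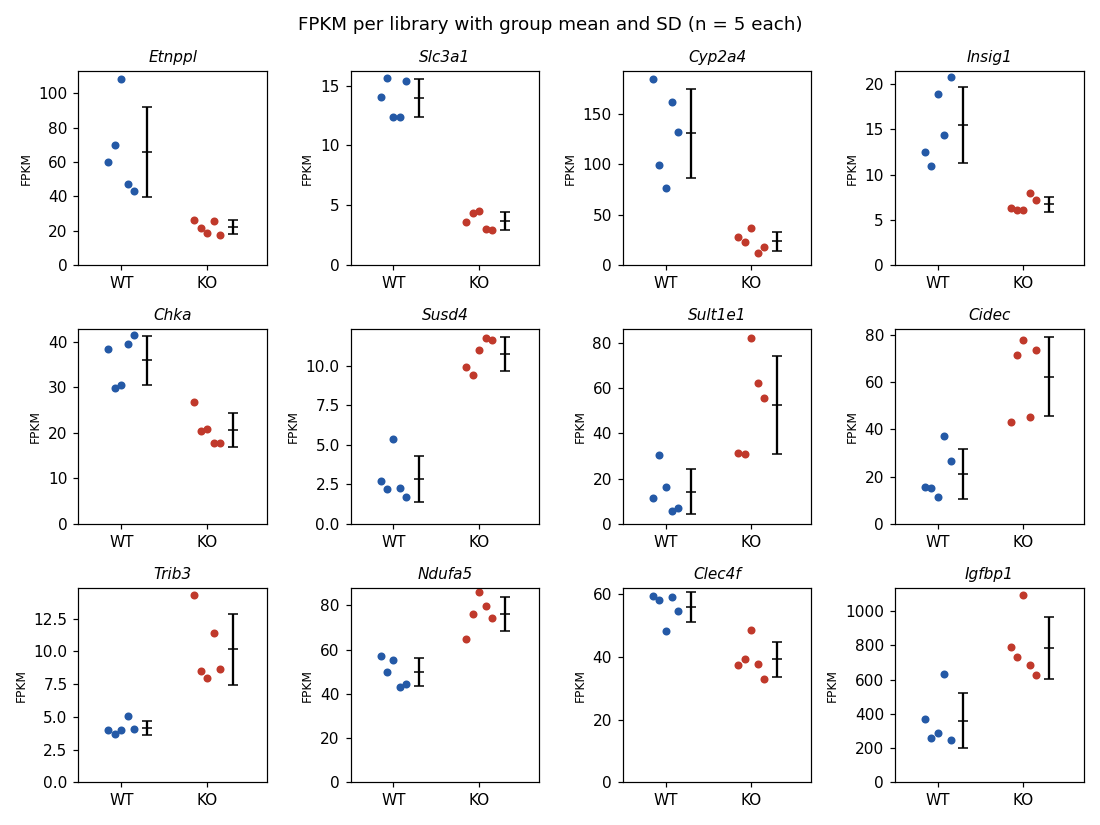
FPKM (vertical axis, from 0) of 12 genes in each of the 5 WT (blue) and 5 KO (red) libraries, with black bars for the group mean and SD. Etnppl lay between 43.32 and 108.39 FPKM in WT and between 17.72 and 26.43 FPKM in KO.

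The comparison of KO with WT asked how loss of Etnppl altered hepatic gene expression. Slc3a1, a subunit of the transporter for cystine and dibasic amino acids, fell from 13.96 ± 1.548 to 3.698 ± 0.7384 FPKM (SD, n = 5 each), a log2 difference of -1.80 (SE 0.12, limma adjusted p = 7.56e-05), and had the smallest p of all genes tested. Cyp2a4, a female-biased cytochrome P450, fell from 130.7 ± 44.02 to 23.83 ± 9.137 FPKM (log2 difference -2.45). Sult1e1, the estrogen sulfotransferase, rose from 14.23 ± 10 to 52.39 ± 21.72 FPKM (log2 difference 1.99), and Cidec, a lipid droplet protein, rose from 21.3 ± 10.59 to 62.36 ± 16.66 FPKM (log2 difference 1.61). Both groups of libraries were separated for each of these genes. For Sult1e1 this was by a narrow margin, with 30.5 FPKM in WT 2 and 30.78 FPKM in KO 2.

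In all, 488 genes were higher and 558 lower in KO at a limma adjusted p under 0.05, which was 8.54% of the genes tested. Which direction held more genes depended on scaling, with 578 higher and 500 lower after median-of-ratios scaling, 542 and 522 after upper-quartile scaling, and 612 and 479 after quantile normalization. Most differences were small, with a median absolute log2 difference of 0.39 among the called genes, and 32 of the higher and 35 of the lower genes changed by at least 1 on the log2 scale. The other large rises with separated groups were Susd4 (1.83), Ly6d (1.74), Olig1 (1.60), Mup21 (1.48), Rarres1 (1.43), Serpina7 (1.43), which encodes thyroxine-binding globulin, Npnt (1.42) and Cyp4a12b (1.39). The other large falls were Gm6135 (-2.13), Sdr9c7 (-1.69), Nxpe2 (-1.62), Gm8941 (-1.59), Pcp4l1 (-1.58), 1500017E21Rik (-1.50) and Gm15375 (-1.46). Cyp2a4, Mup21 and Cyp4a12b belong to families with near-identical copies, so the split of reads among copies is uncertain. The counts of higher and lower genes dropped to 290 and 369 without WT 1, 309 and 453 without WT 4, 266 and 327 without WT 5, 262 and 342 without KO 2, 265 and 361 without KO 4, and 259 and 317 without KO 5. Of 100 called genes that the naming rule gave and the text names, 58 stayed called whichever library was left out. Among the large changes, Sult1e1 lost its call without WT 1, WT 5, KO 4 or KO 5 (adjusted p up to 0.06), Gm6135 without any of 6 libraries (WT 1, WT 2, WT 4, WT 5, KO 3, KO 4; up to 0.073), and Serpina7 and Mup21 without any of 7, which for both included WT 1, WT 5, KO 1, KO 3 and KO 5 (up to 0.085 and 0.074).

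**Figure D2:**
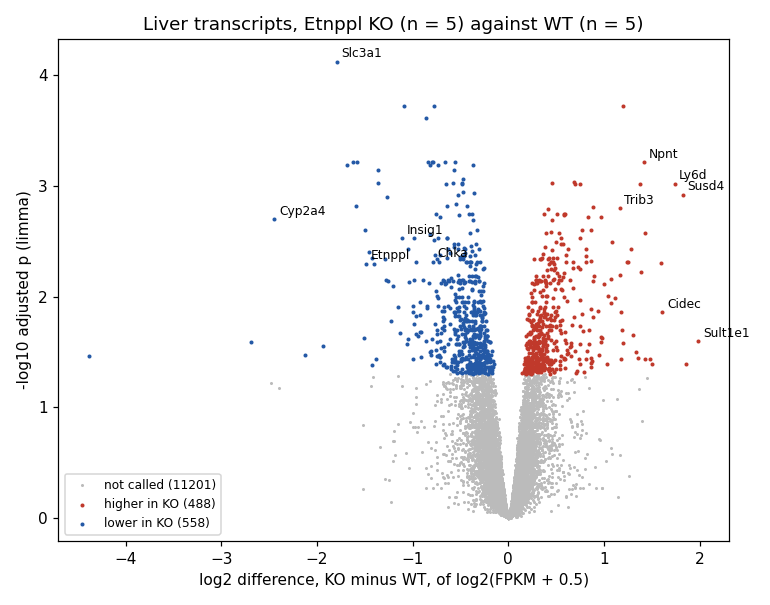
Each point is 1 of the 12247 genes tested, with the log2 difference KO minus WT on the horizontal axis and -log10 of the limma adjusted p on the vertical axis (5 libraries per group). Red marks the 488 genes higher and blue the 558 genes lower in KO, and Slc3a1 has the smallest p.

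Single genes of the pathway that Etnppl belongs to changed. Of 23 tested genes of ethanolamine and choline phospholipid synthesis, 3 fell, 1 rose and 19 did not pass the test (adjusted over the list alone, 4 fell and 2 rose). Chka, a choline kinase, fell from 35.98 ± 5.381 to 20.69 ± 3.735 FPKM (log2 difference -0.79). Etnk1, an ethanolamine kinase, fell by 0.45 on the log2 scale, and Pcyt2, which makes CDP-ethanolamine from phosphoethanolamine, fell by 0.26. Phykpl, the phospho-lyase most similar to Etnppl, rose by 0.36. The list as a whole did not pass camera (median -0.08, camera adjusted p = 0.48). Chka stayed called whichever library was left out. Etnk1 lost its call without WT 1, WT 4, WT 5, KO 1 or KO 2, Pcyt2 without WT 4, WT 5, KO 1, KO 4 or KO 5, and Phykpl without WT 1, KO 2, KO 3, KO 4 or KO 5 (adjusted p up to 0.058, 0.069 and 0.057).

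Of 39 gene lists fixed before the data were examined, 12 passed the camera threshold. None of these calls held with an estimated correlation between genes, where the smallest adjusted p was 0.63, and 4 lists passed with fry, a rotation test (cholesterol synthesis, nuclear oxidative phosphorylation, female-biased genes and ATF4 targets). Among 100 splits of the 10 libraries into 5 and 5, 25, the real one included, gave as many lists. The number of lists therefore did not set the genotypes apart from other splits, and the groups below are described through the tests of their member genes. Over all tested genes 8.54% were called. The 4 of 33 interferon, 2 of 19 endoplasmic reticulum, 2 of 16 gluconeogenesis and 1 of 17 major urinary protein genes called are not far from that share. Such counts alone do not set these 4 lists apart from other genes.

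Cholesterol synthesis genes were lower in KO. Of 26 tested, 12 fell, none rose and 14 did not pass (18 fell adjusted over the list alone), with a median log2 difference of -0.36. Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, fell from 15.5 ± 4.161 to 6.744 ± 0.8367 FPKM (log2 difference -1.11). Ebp fell from 91.47 ± 2.239 to 73.04 ± 3.122 FPKM (-0.32) and Mvd from 1.244 ± 0.1201 to 0.668 ± 0.1262 FPKM (-0.58). The list passed camera with an adjusted p of 9.8e-10 (adjusted p = 0.63 with an estimated correlation, 0.013 with fry). Of 24 genes of fatty acid and triglyceride synthesis, Elovl6 (0.46) and Acaca (0.42) rose and 22 did not pass, Fads1 (-0.21) and Elovl5 (0.23) among them (median 0.02, camera adjusted p = 0.48). Elovl6, which lies within 10 Mb of Etnppl, stayed called whichever library was left out. Acaca lost its call without any of 7, all but WT 1, WT 3 and KO 4 (adjusted p up to 0.084).

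Nuclear genes of oxidative phosphorylation were slightly higher in KO. Of 80 tested, 22 rose, none fell and 58 did not pass (29 rose adjusted over the list alone), and the median log2 difference was 0.13. Ndufa5 rose from 49.98 ± 6.229 to 76.18 ± 7.748 FPKM (log2 difference 0.61), Ndufs4 by 0.38, Atp5g3 by 0.33 and Atp5f1 by 0.27. Risen genes were found in each respiratory complex, with 7 of 36 in complex I, 1 of 4 in complex II, 4 of 9 in complex III, 4 of 13 in complex IV and 5 of 17 in complex V. The camera adjusted p was 7.5e-14 (adjusted p = 0.63 with an estimated correlation, 0.034 with fry).

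Some female-biased liver genes fell and some male-biased liver genes rose in these female KO livers. Of 23 female-biased genes, 8 fell, none rose and 15 did not pass (13 fell adjusted over the list alone), with a median of -1. Acot3 fell from 89.93 ± 26.57 to 32.06 ± 5.361 FPKM (log2 difference -1.43), Cyp17a1 from 225.1 ± 40.86 to 126.1 ± 24.62 FPKM (-0.83) and Abcd2 from 13.56 ± 2.054 to 7.978 ± 1.658 FPKM (-0.74), beside Cyp2a4. Of 20 male-biased genes, 6 rose, none fell and 14 did not pass (6 rose and 1 fell adjusted over the list alone), with a median of 0.27: Susd4, Cyp2u1 (1.25), Cyp4a12b, Cyp2d9 (1.30), Mup21 and Cyp4a12a (1.86). Camera gave adjusted p = 6.4e-06 for the female-biased list (adjusted p = 0.63 with an estimated correlation) and 0.0099 for the male-biased list (adjusted p = 0.70 with an estimated correlation, 0.12 with fry and 0.21 among genes with a mean of at least 5 FPKM). Cyp2d9 lost its call without WT 5, KO 2 or KO 5 (adjusted p up to 0.055) and Cyp4a12a without any of 8 libraries, all but WT 3 and KO 2 (up to 0.083). In WT 3 the female-biased genes lay below the other WT libraries, with a list score of -0.45 against 0.60 to 1.03. Major urinary proteins, a male-biased family of near-identical copies, had a median of 0.20 over 17 genes, of which Mup21 rose and 16 did not pass, Mup16 (0.70), Mup12 (0.69) and Mup20 (0.49) among them. The camera adjusted p was 0.033 (adjusted p = 0.79 with an estimated correlation), but 0.17 among genes with a mean of at least 5 FPKM, 0.052 after median-of-ratios scaling and 0.075 after quantile normalization, and it was 0.11 without WT 1, 0.085 without WT 4, 0.23 without KO 1, 0.14 without KO 3 and 0.051 without KO 5.

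Some transcripts of macrophages, MHC class II presentation and the interferon response fell in KO. Of 18 markers of Kupffer cells, the resident macrophages of the liver, 5 fell, none rose and 13 did not pass (9 fell adjusted over the list alone): Clec4f fell from 55.87 ± 4.736 to 39.14 ± 5.684 FPKM (log2 difference -0.52), and C1qa (-0.46), Vsig4 (-0.43), Csf1r (-0.37) and Folr2 (-0.59) fell too (list median -0.23, camera adjusted p = 0.0015, adjusted p = 0.70 with an estimated correlation). Of 7 genes of MHC class II presentation, H2-Ab1 (-0.40), H2-Eb1 (-0.42) and H2-Aa (-0.40) fell and 4 did not pass, Cd74 (-0.38) among them (4 fell adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.70 with an estimated correlation). Of 33 interferon response genes, Iigp1 (-0.56), Bst2 (-0.41), Irgm1 (-0.55) and Stat2 (-0.34) fell and 29 did not pass (4 fell adjusted over the list alone). The interferon list had a camera adjusted p of 0.004 (adjusted p = 0.79 with an estimated correlation), which became 0.11 without WT 1 and 0.053 without KO 5. The falls of Clec4f, C1qa and Vsig4 stayed called whichever library was left out, while those of Csf1r, Folr2, the 3 MHC class II genes and the 4 interferon genes each lost the call without KO 5 and without other single libraries (adjusted p up to 0.1). None of 16 sinusoidal endothelial markers was called by limma, 0 of them adjusted over the list alone, and their median was -0.05. The Kupffer list score did not separate the genotypes in an exact permutation test (p = 0.1, n = 5 each), nor did its difference from the endothelial score (-0.15, p = 0.17). None of 14 lymphocyte markers (median -0.05) or 3 neutrophil markers (median -0.28) was called by limma. At an unadjusted p under 0.05 there were 4 endothelial, 3 lymphocyte and 0 neutrophil markers. The 3 lymphocyte markers were all lower in KO (Nkg7 -0.531, Jchain -0.477 and Igkc -0.575). Among the endothelial ones Gpihbp1 was higher (0.246), and Stab2 (-0.169), Fcgr2b (-0.145) and Ehd3 (-0.264) were lower.

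Of 19 targets of the amino acid stress factor ATF4, 4 rose and 15 did not pass (4 rose adjusted over the list alone): Trib3 rose from 4.17 ± 0.5288 to 10.16 ± 2.693 FPKM (log2 difference 1.16), and Vldlr (0.65), Psat1 (0.74) and Atf5 (0.39) rose too (camera adjusted p = 0.002, adjusted p = 0.63 with an estimated correlation). Of 19 endoplasmic reticulum chaperone and quality control genes, Edem1 (-0.38) and Syvn1 (-0.47), both of the degradation pathway for misfolded proteins, fell and 17 did not pass, with Sel1l at -0.28 and Xbp1 at -0.24 (2 fell adjusted over the list alone, list median -0.31, camera adjusted p = 0.0015, adjusted p = 0.79 with an estimated correlation). The score of this list did not separate the genotypes (exact permutation test, p = 0.15). It was higher in KO 3 (0.237) and KO 5 (0.181) than in WT 2 (0.065) and WT 3 (-0.312). Of 16 gluconeogenesis genes, Igfbp1, a secreted protein that insulin represses, rose from 360.5 ± 160.4 to 785.4 ± 181.3 FPKM (1.19) and Gpt2 rose by 0.29, while 14 did not pass, with Slc37a4 at 0.32 and Pck1 at 0.25 (2 rose adjusted over the list alone). The camera adjusted p was 0.019 (adjusted p = 0.70 with an estimated correlation), and 0.1 without WT 1, 0.06 without WT 5 and 0.054 without KO 2. Of 5 clock genes of the morning arm, Arntl (-0.47) and Nfil3 (-0.67) fell and 3 did not pass, with Cry1 at -0.43 and Npas2 at -0.32 (2 fell adjusted over the list alone). The camera adjusted p was 0.033 (adjusted p = 0.70 with an estimated correlation), and 0.065 among genes with a mean of at least 5 FPKM, 0.13 without WT 4, 0.06 without WT 5, 0.074 without KO 3 and 0.11 without KO 4. With the replicate number as a block it was 0.06. Trib3, Atf5, Edem1, Syvn1, Igfbp1 and Arntl stayed called whichever library was left out, while Vldlr, Psat1, Gpt2 and Nfil3 each lost the call without WT 5, KO 4, KO 5 and other single libraries (adjusted p up to 0.1).

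**Figure D3:**
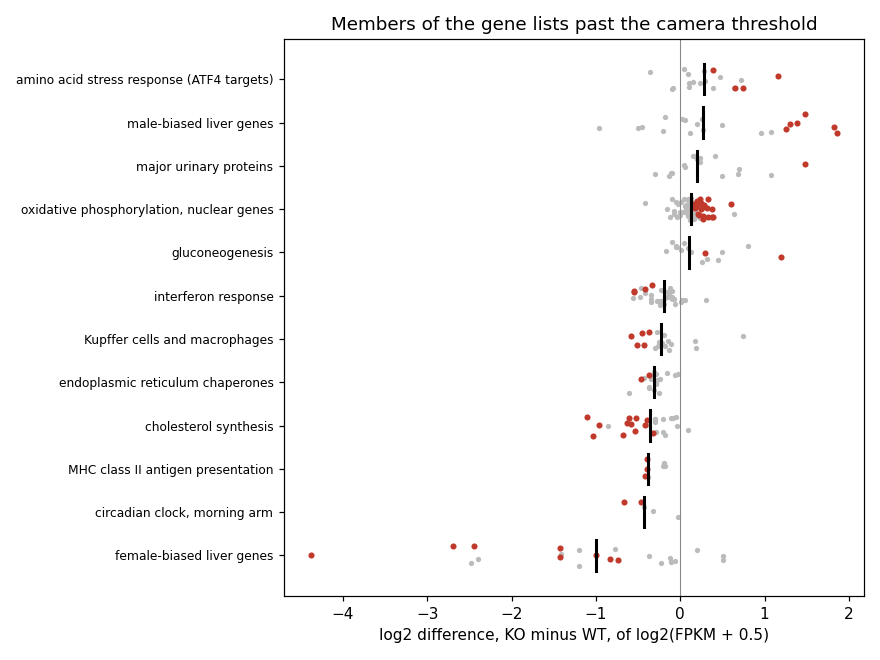
Each point is a tested member of 1 of the 12 gene lists past the camera threshold, placed by its log2 difference KO minus WT (horizontal axis) and spread vertically at random within its list. Red points passed limma's adjusted p, gray points did not, and black bars are list medians, from -1 for female-biased genes to 0.28 for ATF4 targets.

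The chromosomal neighbourhood of Etnppl, where a knockout can keep DNA of the strain it was made in, held a larger share of called genes, by a margin that did not pass the test. Within 10 Mb, 11 of 77 tested genes were called (14.3%), against 1034 of 12142 elsewhere (8.52%), an odds ratio of 1.79 (Fisher's exact test, two-sided, p = 0.096). It was 2.01 within 5 Mb (exact p = 0.13), 1.38 within 20 Mb (exact p = 0.27) and 1.30 with no filter on low values (exact p = 0.51). In the same exact test the excess passed 0.05 after median-of-ratios scaling (2.11, p = 0.023), upper-quartile scaling (2.15, p = 0.022) and quantile normalization (2.09, p = 0.024). It also passed the exact test without WT 3 (2.09, p = 0.033), WT 5 (2.30, p = 0.032), KO 1 (2.83, p = 0.0026), KO 3 (2.40, p = 0.017) or KO 5 (2.71, p = 0.0099). The excess passed with the replicate number as a block too. The 6 with the smallest p were 0610031O16Rik (-0.80), Npnt, Gclm (-0.37), a subunit of the first enzyme of glutathione synthesis, the complement regulator Cfi (-0.40), Cyp2u1 and the alcohol dehydrogenase Adh1 (-0.49). Gclm is counted below among NRF2 targets, and Npnt and Cyp2u1 are counted above too. So are Gm6135 (-2.13) and Elovl6 (0.46), which are called and also lie within 10 Mb. For genes this close, an effect of flanking DNA cannot be told apart from one of Etnppl loss.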

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

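Groups of 5 libraries were searched for 1 library far from the other 4, in the genes named in the text and the 12 lists. Of 262 groups, 11 held such a library, and chance alone gives about 1 in 20, or 13.1. WT 3 accounts for 5 of them. Its female-biased list score was -0.45, against 0.60 to 1.03 in the other WT libraries. Cyp3a16 was at 1.07 FPKM in WT 3 against 34.09 to 86.63 in the others, and Cyp3a44 at 35.16 against 119.93 to 147.37. Mup12 was at 17.2 FPKM in WT 3 against 6.23 to 7.66, and Axin2 at 3.09 against 4.98 to 5.6. WT 3 had the highest Etnppl of all libraries, 108.39 FPKM, and so did not look like a KO library in that gene. Without WT 3 the female-biased list median was -0.94 and the male-biased median 0.25.

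The others were single genes. Acaca was at 8.84 FPKM in KO 4 against 11.07 to 11.78 in the other KO libraries. Cyp2u1 was at 8.4 FPKM in KO 1 against 3.44 to 4.17. Fads1 was at 104.74 FPKM in WT 1 against 89.51 to 93.6. H2-Ab1 was at 14.22 FPKM in KO 5 against 17.77 to 19.22. Pigr was at 441.66 FPKM in KO 1 against 358.84 to 376.75. Rarres1 was at 26.42 FPKM in WT 5 against 38.74 to 43.89.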

How the results depend on the processing

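The 488 higher and 558 lower genes became 294 and 370 with no filter on low values, where 21111 genes were tested, and 32 and 35 with a minimum log2 change of 1, which shrinks the set by construction. Other pseudocounts, a filter at 5 FPKM, 3 scalings, a non-robust fit and library weights kept both counts within 1.5 times, but each scaling made the higher genes the larger group, with 46.7% of calls higher as deposited and 53.6%, 50.9% and 56.1% after median-of-ratios, upper-quartile and quantile scaling. Without 1 library, which leaves fewer samples, higher genes ranged from 259 to 456 and lower genes from 317 to 544, lowest without KO 5 and highest without WT 3. Etnppl stayed lower and past the threshold in each alternative run on it, from -1.62 to -1.29 without 1 library. Replicate numbers are shared by both genotypes, but little pairing of the libraries was seen. Same-numbered deviations correlated at 0.09, 0.16, -0.21, 0.01 and 0.21, and 2 of 5 WT and 2 of 5 KO libraries matched their own number best. So few libraries cannot exclude a pairing. With the replicate block the counts were 230 and 321, of which 510 genes in all were shared with the unblocked calls, and the morning clock list had an adjusted p of 0.06. The odds ratio near Etnppl, 1.79, was 2.84 (p = 0.0074, Fisher's exact test) with the block, 2.11 with median-of-ratios scaling, 2.15 with upper-quartile scaling and 2.09 with quantile normalization, all past the threshold, and ranged from 1.77 to 2.83 without 1 library. The cause was not tested. Of the 12 gene lists, 0 passed with an estimated correlation and 4 with fry. At an unadjusted p under 0.05 the estimated correlation gave 3. Without 1 library, 9 to 15 lists passed. Of 122 called named genes, 20 lost the call without WT 3 and 53 without KO 5, the fewest and the most with 1 library left out. With the replicate block 39 of these genes lost it, and with no filter on low values 46 did. None changed direction in any alternative. Depth in reads was not known, so what it limits among low genes was not estimated.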

Other observations

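Several metabolic groups held genes that moved in both directions. Of 35 tested PPARA targets and fatty acid oxidation genes, 4 rose, 2 fell and 29 did not pass. Cidec (1.61), Ehhadh (0.66) and the fatty acid transporter Slc27a1 (0.48) were among those that rose, while Acot3 (-1.43) and Acadm (-0.24) fell (list median 0, camera adjusted p = 0.48; 5 rose and 4 fell adjusted over the list alone). In glycolysis and glycogen metabolism, 5 of 21 rose and 1 fell (5 and 2 adjusted over the list alone): Eno1 rose from 312 ± 19.33 to 392.8 ± 31.39 FPKM (SD, n = 5 each, log2 difference 0.33), Gbe1 (0.35), Gys2 (0.40) and Pgam1 (0.18) rose too, and Ppp1r3c, a glycogen-targeting phosphatase subunit, fell by 1.06 on the log2 scale (median 0.05, mean -0.02, camera adjusted p = 0.48). In serine, methionine and one-carbon metabolism, 4 of 21 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.48). Mat1a (0.49), Bhmt (0.51) and Psat1 (0.74) were among those that rose. Of 24 lipoprotein and lipid uptake genes, 3 rose (Cd36 0.58, Apoc2 (ENSMUSG00000002992) 0.48 and Apoa2 0.26) and 3 fell (Pltp -0.46, Lrp1 -0.33 and Apoh -0.17), with 5 and 4 adjusted over the list alone (camera adjusted p = 0.65). Ehhadh, Slc27a1, Acadm, Gbe1, Gys2, Pgam1, Ppp1r3c, Psat1, Lrp1 and Apoh each lost the call without KO 4 and without other single libraries (adjusted p up to 0.11), and Apoa2 without KO 4 alone (0.051).

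Secreted and zonated liver genes also moved both ways. Of 25 acute phase genes, 5 fell, among them Itih4 (-0.55), Fga (-0.37) and Steap4 (-0.45), and 2 rose, Apcs (0.75) among them (10 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.12). Of 19 pericentral hepatocyte genes, Rgn (-0.84), Gulo (-0.36) and Axin2 (-0.60) fell and Slc1a2 (0.22) rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.075). Of 19 periportal genes, Cps1 (0.58), Hsd17b13 (0.41) and Cyp2f2 (0.33) rose and Pigr (-0.39), Rnase4 (-0.53) and Ctsc (-0.46) fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.42). Among 18 NRF2 targets, both subunits of glutamate-cysteine ligase fell, Gclm by 0.37 and Gclc by 0.37, and Nqo1 fell by 0.48, while Srxn1 rose by 0.35 (3 and 3 adjusted over the list alone, camera adjusted p = 0.65). Gclm lies within 10 Mb of Etnppl, so for its fall an effect of flanking DNA cannot be told apart from one of Etnppl loss. Of 82 cytosolic ribosomal protein genes, Rpl22l1 (0.49) rose and Rpl41 (-0.19) fell, with Rplp0 at -0.13 and Rpl3 at 0.18 (0 adjusted over the list alone, median -0.03, camera adjusted p = 0.48). Axin2, Slc1a2, Cyp2f2, Ctsc, Gclc, Nqo1, Srxn1, Rpl22l1 and Rpl41 each lost the call without KO 5 and without other single libraries (adjusted p up to 0.11).

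Of the tests that follow, those of the summed Cyp3a genes, the Y-linked genes, the single-copy members, the fatty acid list, the evening minus morning score, the genes near Etnppl and the use of quantile normalization alone to judge scaling were chosen after their results or their members' values were seen. Of 100 splits of the 10 libraries, 1, the real one, gave as many called genes: the real split called 1046, and the highest other called 132. In each direction the same held, with 1 split reaching 488 higher or 558 lower genes against 73 in the larger direction of any other. Such counts are therefore rare among divisions of these libraries, though 100 splits cannot exclude chance. The other splits mix the genotypes, so a difference between genotypes itself lowers their counts. The number of gene lists was not rare in this way, since 25 splits gave 12 or more and the highest other gave 17. For the 11 called genes near Etnppl, 1 split reached the count and the highest other had 0, but other splits called few genes anywhere, so this says nothing about the neighbourhood itself.

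The falls among female-biased and rises among male-biased genes might come from a male liver among the KO libraries, from reads shared among Cyp3a copies, or from a few gene families. The highest level of 4 Y-linked genes in KO was 0.01 FPKM, which argues against male livers. The summed FPKM of Cyp3a11, Cyp3a16, Cyp3a41a, Cyp3a41b and Cyp3a44, named here after their values were seen, fell from 2476 ± 550 to 1341 ± 321 (log2 difference -0.88, exact permutation p = 0.016, n = 5 each). A shift of reads among these 5 copies alone does not give that fall. A shift to Cyp3a copies outside the sum was not tested. The 10 members outside the Cyp2, Cyp3a, Sult and Acot families had a median of -0.43 and a camera p of 0.008. A weaker female pattern of liver expression in KO stays as a hypothesis, with hormone levels and estrous stage not measured here and WT 3 lying near the KO libraries.

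The fall of cholesterol synthesis genes might reflect harvest time or a higher lipogenic state in WT. With an evening minus morning clock score as a covariate, the list median was -0.40 (-0.36 without it). The list still passed camera at the preset correlation, with 6 of its genes called in place of 12 and 481 genes in all. This argues against clock phase as the whole cause only as far as the score measures phase. The score averages evening genes that moved both ways, such as Nr1d1 (0.755) and Per1 (-0.233), neither of them called. The score itself was -0.75 ± 0.51 in WT and -0.22 ± 0.50 in KO, a difference of 0.53 (exact permutation p = 0.13, n = 5 each), so with this spread a phase shift between the groups cannot be told apart from chance. The cholesterol minus fatty acid list score differed by -0.40 (exact permutation test, p = 0.0079, the smallest possible, n = 5 each). The cholesterol score alone gave the same p in the exact permutation test, so the subtraction restates its fall and cannot test a lipogenic change. The fatty acid score did not separate the genotypes (exact permutation test, p = 0.64, n = 5 each), with 12 of its genes higher and 12 lower in KO. No shared fall of both lists was seen, but a higher lipogenic state in WT stays open. Sterol sensing in KO livers is a hypothesis that these data leave open, as sterols were not measured here.

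The rise of oxidative phosphorylation genes could come from transcript length, GC content or scaling, since their median transcript length was 1135 bases against 3175 for all tested genes. After the trend of fold change on length and GC was removed, the list median was 0.13, as before, and the list still passed camera, but that trend held only 1.1% of the variance; ribosomal protein genes, with a median length of 1054 bases, had a median of -0.03, which argues against length. A factor per library shifts all genes alike and cannot part a list from the rest, which argues against such a factor as the cause of the list's difference from other genes. Quantile normalization moved that difference from 0.151 to 0.162, away from 0, but it moved genes apart by little (SD 0.013), so it adds little. Lower relative depth in KO was not tested as an explanation and stays open.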
